A study of Homo sapiens with 24 samples.

How the data were processed

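Poly(A) RNA from 2 human acute myeloid leukaemia cell lines was sequenced after treatment with DMSO (the solvent) or with RMC-7977, an inhibitor that binds the active, GTP-loaded form of RAS proteins, at 25 nM for 2 or 24 h. The labels list 24 libraries in 6 groups, with 4 libraries in each group, and give all of them the same batch. The table used here held 23 library columns. The third library of OCI-AML3 at 24 h was not analysed here, so that group had n = 3. Each column was matched to its sample by the library name in the labels. The labels give each line a single DMSO group and state no time for it, so the same DMSO libraries served both times. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which could be technical.

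The values deposited by the authors were log2 CPM (counts scaled to the effective size of each library) for 13033 gene symbols. Per the submitters' processing notes, the tools were MultiQC 1.28, Trimmomatic 0.36, STAR 2.7.8a, RSEM 1.3.3, edgeR 3.24.3 and limma 3.38.3, with the human genome hg38 (GRCh38). These notes give no order or settings. The strand setting of the counting and the filter on low genes are not given in the sources used here. In the table, every gene reached 1 CPM in at least 2 libraries and 10 reads in at least 3. All libraries shared 1 lowest value, log2 CPM -3.26, which equals 0.105 CPM and a prior count of 1.96 at the mean library size. Fold changes are therefore on the scale of log2 of CPM plus that prior, which understates the change of genes with few reads.

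The depth of each library was recovered from the spacing of its low values. Effective library sizes ran from 15.4 to 22.4 M reads, with a median of 18.5 M. Between 74.7% and 82.4% of the values of up to 20 reads lay within 0.05 of a whole read. The rest were fractional, as estimated counts can be, so no test on counts was used for the main results. Limma voom on recovered read equivalents was run only as an alternative. The planned design assumed counts and a test on counts, and named limma for values on a log scale. Because the unit was log2, limma was the test used here. For named genes with 0 to 3 reads in a group, a ratio of summed reads with its exact 95% interval is given in place of the fitted fold change. Where a group had 0 reads, a lower bound is given against a floor of 3 counts over the whole group. These intervals and bounds cover counting error only. In the differences in response, genes with so few reads in a group are not named.

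All comparisons used limma 3.58.1 in R 4.3.3 on the deposited log2 CPM. A single fit held 6 group means over the 23 libraries, with empirical Bayes moderation (trend and robust options), and each comparison was a contrast of these means. The p-values were adjusted by the Benjamini-Hochberg method over 13033 genes. A gene was called higher or lower at an adjusted p below 0.05 with an absolute log2 fold change of at least 1, and the words rose and fell are used for such genes only. The comparisons were drug against DMSO at each time in each line, 24 h against 2 h in each line, the difference in response between the lines at each time, and the lines against each other in DMSO. A positive difference in response means a higher log2 fold change in OCI-AML3.

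Before the data were examined, 26 gene lists were fixed. Of these, 23 had at least 5 measured members and were tested with camera in limma at its preset correlation of 0.01, and the other 3 are given as counts. The tests were adjusted over 92 tests of drug against DMSO and over another 92 tests of times and lines. Camera with an estimated correlation and fry, which tests a list without comparing it with other genes, were run beside it. The preset correlation called 49 of the tests against DMSO, and 35 of these held with an estimated correlation. In the other family it called 53, and 35 of these held. Counts of members adjusted over the list alone equalled the counts over all genes in every pair of list and comparison but 1 of 208. The exception was the heat shock list in Molm-14 at 2 h, where 2 members rose when adjusted over the list alone and 1 over all genes.

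A rule fixed in advance also chose genes to be named. For drug against DMSO it took the 8 largest rises and the 8 largest falls among called genes with at least 5 CPM in the higher group, with every treated library (3 in OCI-AML3 at 24 h) on the same side of all DMSO libraries. For other comparisons it took 5 in each direction. It added up to 4 members of each list with the smallest adjusted p, and 19 genes of the RAS pathway, its targets and the BCL2 family in every case. Read-through and antisense names were left out. Genes named outside this rule, among them further members of the lists, were chosen after their values were seen. Not each of them is marked where it is named. Genes of the sex chromosomes were left out of the description, and the results of some named genes are not reported here. Gene positions come from GENCODE release 29 on GRCh38, in which 12307 of the 13033 symbols were found. Reads of near-identical genes can be assigned to the wrong copy, so values of HSPA6 and HSPA7, FCGR2B and FCGR2C, NCF1 and NCF1C, UPK3BL2, PSMC1P1, HLA genes and histone genes are uncertain.

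Libraries of a group were compared before averaging. No pair shared identical values above the lowest, and the chi-square per gene between libraries of a group was 1.85 to 12.6, so none agreed within sampling noise. The fit was tested on simulated data for 13033 genes, in which 67 genes were changed 1.5-fold, 67 were changed 3-fold and 66 were changed 6-fold. In the 4 comparisons with DMSO, 98.5% to 100% of the genes changed 3-fold or 6-fold were called. Of those changed 1.5-fold, which lie under the bound on the fold change, 0 were called, or 1 of 67 in OCI-AML3 at 2 h, and 50 to 58 had an adjusted p below 0.05. Between 2 and 5 unchanged genes were called. The test of lists, simulated for OCI-AML3 at 24 h, recovered the list that was shifted and called 0 of the other lists. The genes changed 1.5-fold to 6-fold all had at least 1 CPM in DMSO, and far fewer were changed than were called in the data. Genes were drawn independently, so these simulations do not show how the tests behave when the genes of a list are correlated.

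Alternatives fixed in advance were limma voom on recovered read equivalents, library totals without the deposited scaling, a pseudocount of 0.1 CPM, a filter of 1 CPM in 4 libraries, fits of fewer groups, a replicate block, a threshold test against a fold of 1.5, no bound on the fold change, and leaving out each library in turn. Median-of-ratios scaling, a pseudocount of 1 CPM, and library totals for the lists and for the correlation between lines were added after seeing the data. A table without a filter on low genes was not used here.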

Results

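Inhibition of active RAS lowered most transcripts that report ERK signalling within 2 h in both leukaemia lines, Molm-14 (FLT3-ITD) and OCI-AML3 (NRAS Q61L). At 24 h the lines had parted. DUSP6 was back at its DMSO level in Molm-14 and stayed lost in OCI-AML3. MYC and part of its ribosome biogenesis genes fell in both lines at 2 h. Most DNA replication genes fell in both at 24 h, more deeply in OCI-AML3. Interferon response genes were higher in both lines at 24 h. Changes below are log2 fold changes ± SE with n = 4 libraries per group, except OCI-AML3 at 24 h (n = 3). The first principal component of all genes held 75.6% of the variance and the second 15.3%.

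DUSP6 (chr12:89347232-89353271, minus strand) went from 43.9 CPM in DMSO to 2.75 CPM at 2 h and 42.4 CPM at 24 h in Molm-14. In OCI-AML3 it went from 11.8 to 0.201 and 0.170 CPM. MYC (chr8:127735434-127741434, plus strand) went from 601 to 62.6 and 319 CPM in Molm-14, and from 374 to 72.3 and 56.1 CPM in OCI-AML3. CCND1 (chr11:69641087-69654474, plus strand) went from 33.1 to 3.0 and 9.51 CPM in Molm-14, and from 64.4 to 2.16 and 0.428 CPM in OCI-AML3. The pro-apoptotic gene BMF (chr15:40087890-40108892, minus strand) went the other way, from 14.6 to 81.5 and 170 CPM in Molm-14 and from 5.30 to 59.1 and 126 CPM in OCI-AML3.

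**Figure D1:**
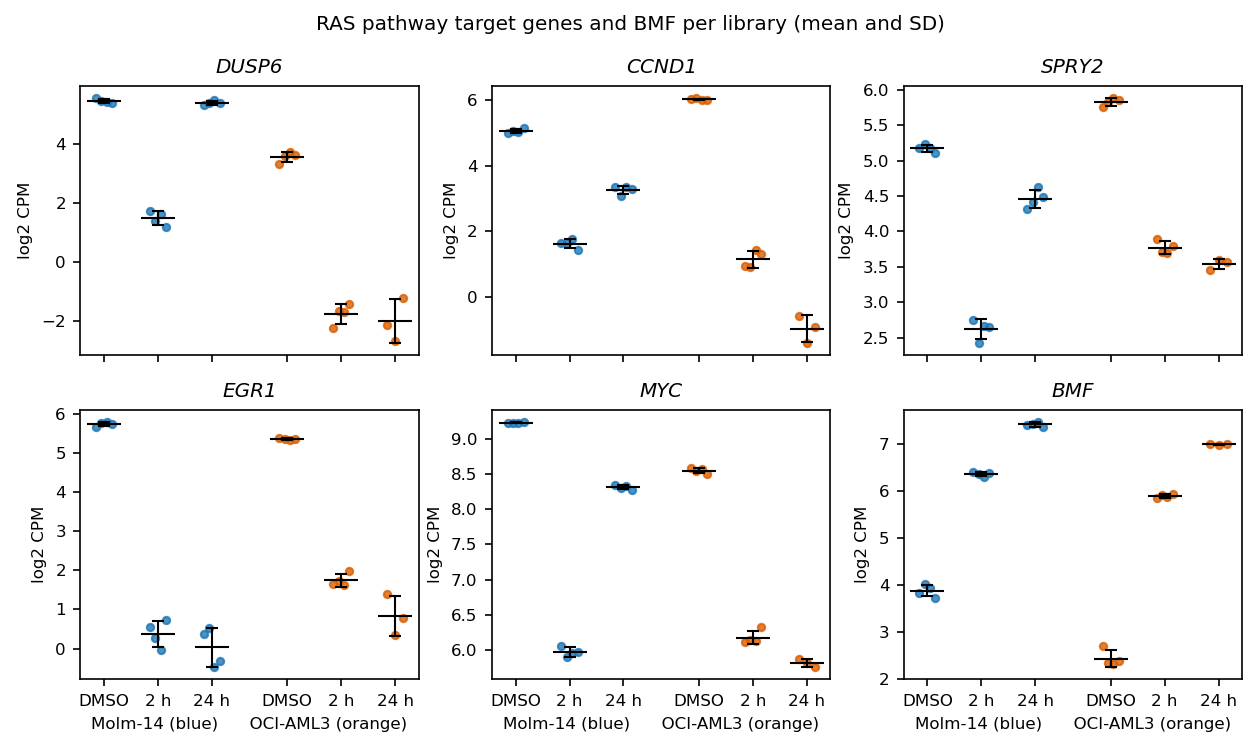
Expression (log2 CPM, vertical axis) of DUSP6, CCND1, SPRY2, EGR1, MYC and BMF in DMSO and after 2 and 24 h of RMC-7977 in Molm-14 (blue) and OCI-AML3 (orange); each point is 1 library, dashes mark group means and bars are SD. DUSP6 means ± SD were 5.46 ± 0.07, 1.5 ± 0.24 and 5.41 ± 0.07 in Molm-14 and 3.57 ± 0.18, -1.74 ± 0.34 and -2.0 ± 0.74 in OCI-AML3.

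In Molm-14 at 2 h, feedback regulators and early targets of ERK fell together. MYC fell with part of its ribosome biogenesis programme. Part of the NF-kB and inflammatory genes fell as well, and so did TNF. KLF2, the cell-cycle inhibitor CDKN1C and the BH3-only genes BMF and BBC3 were among the genes that rose. The S phase list as a whole was not called.

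The drug called 950 genes in Molm-14 at 2 h, 561 higher and 389 lower, and 7756 genes had an adjusted p below 0.05. The largest rises were KLF2 (chr19:16324817-16327874, plus strand; 6.61 ± 0.09, adjusted p = 6.7e-26), CDKN1C (chr11:2883213-2885773, minus strand; 4.99 ± 0.28), MAFA (4.95 ± 0.26), CRIP2 (4.92 ± 0.19), KIAA1522 (4.78 ± 0.18) and FGFR3 (4.57 ± 0.07). ENHO and RHOB, nearly silent in DMSO, rose 195-fold (interval 53.6 to 1613) and 124-fold (42.2 to 605). The largest falls were EGR1 (chr5:138465490-138469315, plus strand; -5.37 ± 0.20, adjusted p = 2.6e-19), SPRY4 (chr5:142310427-142326455, minus strand; -5.34 ± 0.19), RGS16 (-5.03 ± 0.07), TNF (-4.18 ± 0.10), DUSP6 (-3.96 ± 0.20, adjusted p = 1.1e-16), FOSL1 (-3.56 ± 0.16), F3 (-3.56 ± 0.08) and CCND1 (-3.42 ± 0.13).

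Of 16 genes of ERK output and feedback, 15 fell (median -2.35, adjusted p = 2.99e-10), including SPRY2 (chr13:80335976-80340951, minus strand; -2.55 ± 0.07), ETV5 (chr3:186046308-186110318, minus strand; -2.83 ± 0.15), ETV4 (chr17:43527844-43579620, minus strand; -1.12 ± 0.23) and PHLDA1 (chr12:76025447-76033932, minus strand; -1.09 ± 0.10). The call of PHLDA1 ended with a pseudocount of 1 CPM (-0.95) and without DMSO replicate 4 (-0.99). MYC fell (-3.3 ± 0.04, adjusted p = 4.3e-31). In the list of MYC and ribosome biogenesis 12 of 32 genes fell (median -0.90, adjusted p = 1.18e-19), among them RRS1 (-1.80), POLR1B (-1.31) and GNL3 (-1.15). The immediate early list was split, with 6 of 24 higher and 5 lower (median 0.18, adjusted p = 0.144): JUN (2.46), KLF6 (2.33) and NR4A1 (1.88) rose, and EGR3 (-1.64), FOS (-1.33) and DUSP2 (-1.29) fell.

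Of 16 NF-kB targets 5 fell (median -0.41, adjusted p = 0.00176), among them TNFAIP3 (-3.05), IL1B (-1.85) and CXCL8 (-1.74). CXCL10 was also among them (-2.56), and its call ended with a pseudocount of 1 CPM (-0.96). The BCL2 family as a whole was not called against other genes (median 0.06, adjusted p = 0.962), yet BMF (2.48 ± 0.06), BBC3 (2.31 ± 0.08) and BIK (1.07) rose and BCL2A1 (-2.55) fell. BCL2 itself (chr18:63123346-63320128, minus strand) was at -0.79, MCL1 at -0.41, BCL2L11 at 0.17 and BCL2L1 at 0.10, none of them called. In the RAS pathway list 3 of 31 rose (median 0.18, adjusted p = 0.000392), among them RRAS (1.49) and RASGRP2 (1.37). NRAS (chr1:114704469-114716894, minus strand; 0.14), HRAS (0.04), FLT3 (chr13:28003274-28100592, minus strand; 0.22) and CDKN1B (0.20) were not called.

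Smaller shifts of lists accompanied these. Heat shock and chaperone genes were lower (median -0.38, adjusted p = 3.95e-05), with XBP1 (-1.66) and HSPA8 (-1.07) falling and HSPB1 (1.33) rising; adjusted over the list alone, 2 rose and 2 fell. Integrated stress response genes were lower (median -0.34, adjusted p = 0.000174; STC2 -1.68, SLC7A5 -1.46), and lysosome and autophagy genes were higher (median 0.24, adjusted p = 0.000175; ULK1 1.72). FOXO target genes were higher (median 0.58, adjusted p = 0.00588, adjusted p = 0.0638 with an estimated correlation), with CCNG2 (1.47), KLHL24 (1.47) and YPEL5 (1.36) rising and CITED2 (-1.3) falling. Glycolysis (median -0.12, adjusted p = 0.0207, adjusted p = 0.316 with an estimated correlation) had 3 falls, HK2 (-1.90), PFKFB3 (-1.19) and SLC2A3 (-1.03). Cholesterol synthesis stood at a median of -0.27 (adjusted p = 0.0194, adjusted p = 0.134 with an estimated correlation) with 0 genes called.

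Lists without a call at this time included S phase (median -0.05, adjusted p = 0.73; E2F2 rose by 1.25 and CDC25A fell by 1.12), G2 and M phase (0.04, 0.669), p53 targets (0.18, 0.259), monocyte genes (-0.09, 0.46), granulocyte genes (0.07, 0.943) and HOX and progenitor genes (-0.05, 0.0503; MYB fell by 1.07). The HOX list was called with library totals (adjusted p = 0.0398), with median-of-ratios scaling (adjusted p = 0.0443) and without some single libraries. Also without a call were growth factor receptors (0.01, 0.64), interferon response (0.17, 0.238), MHC class I (0.03, 0.896), MHC class II (-0.06, 0.863) and the mitochondrial chain (-0.06, 0.278). Within them IRF9 (1.85), ISG20 (1.38), IRF7 (1.09), PHLDA3 (1.79), TP53I3 (1.21), LGALS3 (1.54) and AXL (1.34) rose. PLK3 (-1.95), AEN (-1.4), CD1D (-1.94), TLR2 (-1.02), TGFBR1 (-1.42), CCR2 (-1.13) and CSF2RB (-1.10) fell. Of the untested lists, the lymphoid had TRAC (-1.70) lower, the erythroid and platelet 0 called, and the epithelial and stromal PECAM1 (1.0) higher, a call that ended with a pseudocount of 1 CPM.

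In OCI-AML3 at 2 h most ERK output genes fell as well. The fall was deeper than in Molm-14 for CCND1 and shallower for EGR1. MYC and part of its ribosome genes fell, as in Molm-14. The genes that rose included FOXO targets and interferon response genes, and FLT3 rose as well.

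The drug called 858 genes in OCI-AML3 at 2 h, 421 higher and 437 lower, and 8106 had an adjusted p below 0.05. With library totals the balance turned, to 510 higher and 384 lower. The largest rises were ENHO (4.18 ± 0.17), CDKN1C (4.14 ± 0.28), BMF (3.46 ± 0.06, adjusted p = 5.6e-27), SH2D3C (2.73 ± 0.15), KLHL24 (2.57 ± 0.06), ARRDC3 (2.55 ± 0.09), SAMD9L (2.53 ± 0.10) and LINC02724 (2.41 ± 0.17). The largest falls were SPRY4 (-5.70 ± 0.19, adjusted p = 7.3e-21), DUSP6 (-5.31 ± 0.20), CCND1 (-4.85 ± 0.13, adjusted p = 3.3e-23), GPR3 (-4.61 ± 0.25), GPR84 (-4.23 ± 0.14), TNF (-3.79 ± 0.10), EGR1 (-3.62 ± 0.20) and FOSL1 (-3.56 ± 0.16).

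Of the 16 ERK output genes 12 fell (median -2.01, adjusted p = 4.82e-10), with ETV5 at -2.71, SPRY2 at -2.06 and PHLDA1 at -1.97. ETV4 (-0.91) was not called, and without 2 h replicate 4 it was (-1.0, adjusted p = 0.00214). MYC fell (-2.37 ± 0.04, adjusted p = 4.3e-27). In the list of MYC and ribosome biogenesis 14 of 32 genes fell (median -0.89, adjusted p = 4.08e-20), such as RRS1 (-1.56) and RRP12 (-1.34). FOXO target genes were higher (median 0.62, adjusted p = 1.42e-05, 7 of 18 rose; CCNG2 2.28, CREBRF 1.77, TXNIP 1.68), as were interferon response genes (median 0.25, adjusted p = 0.00184, 8 of 25 rose; IFIT2 2.55, STAT2 1.53, IRF7 1.17, IRF9 1.07). Heat shock genes (median -0.68, adjusted p = 1.49e-09; XBP1 -1.41, HSPA1B -1.31, HSPA8 -1.25) and integrated stress response genes (median -0.22, adjusted p = 0.000394; SLC7A5 -2.05, TRIB3 -1.49, SLC7A1 -1.10) were lower. S phase genes were slightly lower (median -0.15, adjusted p = 0.0015), with CCNE2 (-1.4) and CDC25A (-1.32) falling.

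Cholesterol synthesis was lower (median -0.39, adjusted p = 2.67e-05). Glycolysis stood at a median of -0.29 (adjusted p = 1.19e-05, adjusted p = 0.0638 with an estimated correlation), with SLC16A1 (-1.03) and SLC2A1 (-1.0) falling. Both calls ended with library totals (-0.96 and -0.93) and without single libraries. G2 and M phase genes stood at 0.11 (adjusted p = 0.00772, adjusted p = 0.188 with an estimated correlation), with CDC25C (1.07) the only rise. Lysosome genes stood at 0.18 (adjusted p = 0.00234, adjusted p = 0.0826 with an estimated correlation) with 0 called.

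Lists without a call were immediate early (median -0.27, adjusted p = 0.412; DUSP2 fell by 3.4), NF-kB (-0.24, 0.0691; CXCL1 -2.18 and TNFAIP3 -2.01 fell, NFKBIZ 1.08 rose), BCL2 family (-0.08, 0.641; BCL2A1 -2.96 and PMAIP1 -1.52 fell, BBC3 1.11 rose) and p53 (0.01, 0.896; PLK3 -2.79 and AEN -1.58 fell). Monocyte (-0.07, 0.284; CD14 -2.55 fell, CSF1R 1.11 rose), granulocyte (0.12, 0.536), HOX (0.07, 0.87), RAS pathway (0.02, 0.46), receptor (0.11, 0.46; IL10RA 1.41 rose, TGFBR1 -1.24 fell), MHC class I (0.13, 0.46), MHC class II (0.40, 0.261) and mitochondrial chain (0.02, 0.858) genes did not pass either. With library totals the NF-kB list did (adjusted p = 0.0345). FLT3 rose (1.12 ± 0.04, adjusted p = 1.6e-20). Not called were NRAS (0.03), HRAS (-0.53), CDKN1B (0.47), MCL1 (-0.46), BCL2L11 (0.30), BCL2 (-0.06) and BCL2L1 (-0.03). IL7R (-1.36) fell in the untested lymphoid list.

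In Molm-14 at 24 h, ERK output had returned in part. DUSP6 and PHLDA1 stood at DMSO levels and EGR1, SPRY4 and ETV4 stayed low. Most replication, integrated stress response and chaperone genes fell. Part of the monocyte and macrophage genes rose, including CSF1R, CD86 and FCGR2A.

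The drug called 2337 genes, 1481 higher and 856 lower, and 9950 had an adjusted p below 0.05. The largest rises were MAFA (6.88 ± 0.26), LSP1 (6.17 ± 0.12), HSPA7 (6.13 ± 0.12), PNCK (5.71 ± 0.27), FCGR2B (5.65 ± 0.07), FCGR2C (5.61 ± 0.10), JPH2 (5.25 ± 0.27) and HSPA6 (5.07 ± 0.11). The largest falls were EGR1 (-5.72 ± 0.20), ANGPT1 (-5.45 ± 0.31), TNF (-4.21 ± 0.10), CHAC1 (chr15:40952962-40956519, plus strand; -3.99 ± 0.23), SNRNP25 (-3.60 ± 0.56), SLC6A9 (-3.53 ± 0.26), ASNS (-3.51 ± 0.07) and INHBE (-3.22 ± 0.28). With library totals, which shift the balance of rises and falls, the calls were 1728 higher and 629 lower.

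Of the ERK output genes 6 fell (median -0.49, adjusted p = 0.0171), including SPRY4 (-3.10 ± 0.19), ETV4 (-2.74 ± 0.23), CCND1 (-1.79 ± 0.13) and ETV5 (-1.77 ± 0.15). DUSP6 (-0.05 ± 0.20, adjusted p = 0.83), PHLDA1 (-0.06), SPRY2 (-0.71) and MYC (-0.91) were not called. MYC and ribosome genes nonetheless stayed down, with 22 of 32 lower (median -1.19, adjusted p = 6.08e-15; ODC1 -1.66, HSPD1 -1.44, MRTO4 -1.39). S phase genes fell, 29 of 35 (median -1.29, adjusted p = 9.65e-16; RRM2 -1.78, MCM6 -1.5, MCM4 -1.35), and 7 of 28 G2 and M phase genes did (median -0.82, adjusted p = 5.77e-10; CCNA2 -1.35, AURKA -1.15). Integrated stress response genes fell, 20 of 24 (median -1.62, adjusted p = 1.7e-11; PSAT1 -2.75, GARS1 -1.78, SLC3A2 -1.76), and so did 13 of 18 heat shock genes (median -1.24, adjusted p = 1.76e-08; HSPA8 -1.80, HSPA5 -1.74).

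Monocyte and macrophage genes rose, 13 of 28 (median 0.84, adjusted p = 0.000394): CSF1R (3.64 ± 0.06), CD86 (3.55), FCGR2A (chr1:161505430-161524013, plus strand; 2.90) and ITGAX (2.81) rose and FCGR1A (-1.15) fell. Interferon response genes rose, 13 of 25 (median 1.09, adjusted p = 0.00273; ISG20 2.75, IRF9 1.78, STAT2 1.66), as did FOXO target genes, 10 of 18 (median 1.44, adjusted p = 0.000124; YPEL5 2.96, TXNIP 2.46, KLHL24 2.19), with GADD45A (-1.24) falling. Of 5 measured MHC class II genes, from a list of 12, 4 rose (median 1.64, adjusted p = 0.0343, adjusted p = 0.0638 with an estimated correlation): HLA-DMA (1.99), HLA-DRA (1.80), HLA-DRB1 (1.64) and CIITA (1.14). Lysosome genes were higher (median 0.42, adjusted p = 1.7e-05; PSAP 1.37, GRN 1.15). Cholesterol synthesis genes stood at 0.50 (adjusted p = 0.0047, adjusted p = 0.0761 with an estimated correlation), with LSS (1.32), MSMO1 (1.19) and STARD4 (1.10) rising. Mitochondrial chain genes stood at -0.58 (adjusted p = 2.9e-07, adjusted p = 0.164 with an estimated correlation), with 1 called lower.

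Lists without a call were immediate early (median 0.04, adjusted p = 0.492; KLF2 4.69, BTG2 2.57 and KLF6 1.63 rose), BCL2 family (-0.09, 0.863), p53 (0.37, 0.189; TP53INP1 2.64 rose, GDF15 -2.51 and AEN -1.24 fell), granulocyte (0.09, 0.736; CSF3R 1.5 rose, MPO -2.15 fell) and HOX (0.06, 0.439). The RAS pathway (0.22, 0.0729; RASGRP4 2.79, RRAS 2.17, KSR1 1.44 and SOS2 1.04 rose), receptors (0.17, 0.439; TNFRSF1B 3.0 and IL10RA 2.62 rose), MHC class I (0.25, 0.32; HLA-E 1.13 rose, TAP2 -1.37 fell), NF-kB (-0.50, 0.128; TRAF1 2.52 rose, RELB -1.34 fell) and glycolysis (-0.13, 0.863; SLC2A1 1.85 rose, SLC16A1 -1.37 fell) did not pass. With library totals the RAS pathway list did (adjusted p = 0.0394). CXCL10 was 28.4-fold lower (interval 9.39 to 141). BMF rose (3.53 ± 0.06, adjusted p = 6.1e-28), BBC3 rose (1.16) and PMAIP1 fell (-1.33). Not called were BCL2 (-0.82), BCL2L11 (0.60), FLT3 (0.60), HRAS (-0.56), CDKN1B (0.21), NRAS (-0.19), MCL1 (-0.13) and BCL2L1 (-0.05). In the untested lists TRAC (-1.75) and PAX5 (-1.24) fell and ITGA2B (2.21) rose, and 0 epithelial or stromal genes were called. The calls of HOXB3 (1.65) and ITGA2B ended with a pseudocount of 1 CPM (0.70 and 0.86).

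OCI-AML3 at 24 h showed the widest change of the series. ERK output stayed low, MYC stayed low, and nearly every gene of ribosome biogenesis, DNA replication and mitosis in the lists fell. TERT and part of the cholesterol synthesis genes fell as well. HLA-DRA and HLA-DRB1 came on from near silence, and CSF1R and part of the interferon response and lysosome genes rose. BCL2 fell while BMF and BCL2L11 rose.

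The drug called 4620 genes, 2392 higher and 2228 lower, and 11002 had an adjusted p below 0.05. The largest rises included CDKN1C (6.71 ± 0.30), SCARA5 (6.61 ± 0.39), GUCY2D (5.96 ± 0.36), ENHO (5.90 ± 0.18) and PLD4 (5.57 ± 0.09). HLA-DRA rose 516-fold (interval 142 to 4268), JPH2 280-fold (77 to 2320) and UPK3BL2 at least 353-fold. The largest falls included CCND1 (-6.96 ± 0.14, adjusted p = 1.3e-27), TERT (-6.39 ± 0.12), ETV4 (-6.0 ± 0.25, adjusted p = 1.1e-15), HSD11B1 (-5.67 ± 0.12), DUSP6 (-5.56 ± 0.21, adjusted p = 2.4e-20) and DUSP2 (-5.49 ± 0.13). SLCO4A1 was 567-fold lower (194 to 2750) and ABCB4 154-fold lower (42.3 to 1274). Library totals moved the median of all genes from 0.01 to 0.18 here, with 2889 higher and 1820 lower.

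Of the ERK output genes 14 fell (median -2.49, adjusted p = 9.28e-05), among them SPRY4 (-4.62 ± 0.21), ETV5 (-4.03 ± 0.16), SPRY2 (-2.29 ± 0.08) and PHLDA1 (-1.75 ± 0.11), and 1 rose, SPRED3 (2.14), picked out after its value was seen. EGR1 (-4.53 ± 0.21) and MYC (-2.74 ± 0.05, adjusted p = 1.3e-29) fell. Of MYC and ribosome genes 31 of 32 fell (median -2.50, adjusted p = 5.74e-15; ODC1 -3.06, MRTO4 -3.0). S phase genes fell, 34 of 35 (median -2.97, adjusted p = 9.4e-17; CDC45 -4.81, RRM2 -3.94, UHRF1 -3.49, MCM4 -3.37), and 27 of 28 G2 and M phase genes did (median -1.92, adjusted p = 2.52e-12; CCNA2 -2.7, CDC20 -2.43, BIRC5 -2.29, CCNB1 -2.06). Heat shock genes fell, 16 of 18 (median -2.04, adjusted p = 2.19e-08; HSPA8 -3.19, HSPH1 -2.84, HSPA5 -2.47, CALR -2.32), as did 10 of 21 cholesterol synthesis genes (median -0.92, adjusted p = 2.28e-05; TMEM97 -2.67).

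Interferon response genes rose, 14 of 25 (median 1.29, adjusted p = 0.000379; STAT2 3.5, RSAD2 3.05, OAS1 2.92), with USP18 (-1.55) falling. All 5 measured MHC class II genes, from a list of 12, rose (median 2.67, adjusted p = 0.00409), with HLA-DRB1 204-fold higher (56.0 to 1695), HLA-DMA at 2.67, CIITA at 2.39 and CD74 at 1.31. The HLA-DP and HLA-DQ genes of the list were not measured. FOXO genes rose, 10 of 18 (median 1.25, adjusted p = 0.000147; KLHL24 4.25, TXNIP 3.02), and 11 of 29 lysosome genes did (median 0.89, adjusted p = 7.12e-06; GABARAPL1 2.77, GRN 1.69, PSAP 1.64, SQSTM1 1.48). Monocyte genes were divided, with 17 of 28 higher and 6 lower (median 1.41, adjusted p = 0.00559, adjusted p = 0.0638 with an estimated correlation). CSF1R (3.71) and LYZ (2.72) rose, and CD14 (-3.56), FCGR1A (-2.96) and FCN1 (-2.86) fell.

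Glycolysis genes fell, 11 of 20 (median -1.19, adjusted p = 0.000263, adjusted p = 0.116 with an estimated correlation; SLC16A1 -2.64, LDHA -2.16, PGK1 -1.90). Integrated stress response genes stood at -1.03 (adjusted p = 0.00326, adjusted p = 0.0795 with an estimated correlation), with SLC7A5 (-5.21), PSAT1 (-4.30) and PHGDH (-3.16) among 12 falls and SLC7A11 (chr4:138164097-138242349, minus strand; 1.96), VEGFA (1.62) and CEBPB (1.48) rising. Mitochondrial chain genes stood at -0.71 (adjusted p = 3.82e-07, adjusted p = 0.167 with an estimated correlation), with 8 falls (UQCRQ -1.70, COX7B -1.51). Receptor genes stood at 0.61 (adjusted p = 0.0079, adjusted p = 0.103 with an estimated correlation), with CSF2RA (4.0) and IL10RA (2.84) rising. Without a call were immediate early (median 0.16 but mean -0.51, adjusted p = 0.722), NF-kB (-0.36, 0.458), p53 (0.34, 0.121; TP53INP1 2.99 and CDKN1A 1.21 rose), granulocyte (0.10, 0.677; MMP9 -3.39 fell), HOX (0.15, 0.284), RAS pathway (-0.10, 0.722), MHC class I (0.60, 0.0782; HLA-F 1.43 and TAP1 1.12 rose, TAP2 -1.58 fell) and the BCL2 family (-0.39, 0.412).

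Within the BCL2 family, BMF (4.56 ± 0.07, adjusted p = 1.4e-30), BBC3 (1.96) and BCL2L11 (1.10 ± 0.14) rose and BCL2A1 (-4.57), PMAIP1 (-2.65) and BCL2 (-1.47 ± 0.06) fell. The call of BCL2L11 ended without 24 h replicate 4 (0.97). FLT3 rose (1.49 ± 0.04, adjusted p = 3.7e-24) and HRAS fell (-1.18 ± 0.08). Not called were NRAS (-0.38), MCL1 (-0.42), CDKN1B (0.36) and BCL2L1 (-0.24). In the untested lists IL7R (-4.20) fell and ITGA2B (2.7), PECAM1 (1.18) and COL1A2 (1.3) rose; COL1A2 was at 0.96 and not called with a pseudocount of 1 CPM.

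**Figure D2:**
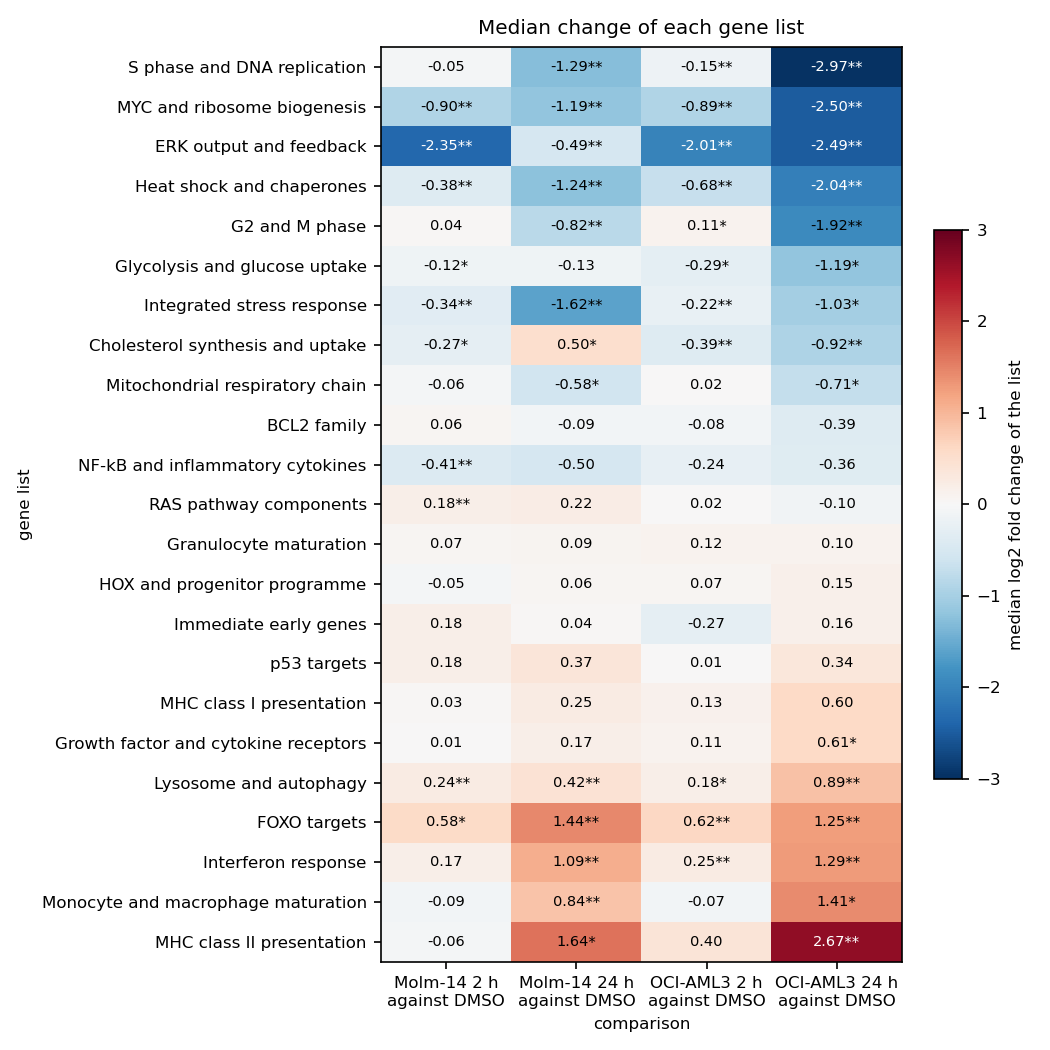
Median log2 fold change (colour) of 23 gene lists, listed down the side, in the 4 comparisons of RMC-7977 with DMSO along the top; a star marks a camera adjusted p below 0.05 and a double star a call that also held with an estimated correlation. The S phase list had medians of -0.05 and -1.29 in Molm-14 and -0.15 and -2.97 in OCI-AML3 at 2 and 24 h.

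Between 2 and 24 h the treated Molm-14 cells regained ERK output and MYC. DUSP6 rose by 3.91 ± 0.20 (adjusted p = 8.9e-17), MYC by 2.35 ± 0.04, SPRY4 by 2.24, SPRY2 by 1.84, CCND1 by 1.63, ETV5 by 1.1 and PHLDA1 by 1.03. ETV4 fell further (-1.62 ± 0.23), BMF rose further (1.1), and EGR1 was not called (-0.35). Of 16 ERK output genes 11 rose and 1 fell (median 1.42, adjusted p = 1.61e-05). The calls of SPRY4, ETV5 and PHLDA1 ended with a pseudocount of 1 CPM, that of ETV5 also without 24 h replicate 3 (0.96), and that of PHLDA1 without 2 h replicate 1 (0.98) or 24 h replicate 4 (0.95).

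This comparison called 1385 genes, 945 higher and 440 lower (8901 by adjusted p alone). HSPA7 (6.43), FCGR2B (6.14), HSPA6 (5.74), FCGR2C (5.60) and LSP1 (5.26) rose most. PSMC1P1 (-4.89 ± 1.5), RHOB (-4.56), CRIP2 (-3.73), CHAC1 (-3.48) and SLC6A9 (-3.42) fell most. S phase (median -1.24, adjusted p = 5.24e-21, 32 of 35 lower), G2 and M phase (-0.83, 6.74e-14), integrated stress response (-1.31, 7.02e-12) and heat shock genes (-0.82, 1.1e-07) were lower. Monocyte (1.09, 1.6e-07), cholesterol (0.65, 7.79e-06), FOXO (0.76, 0.000393), interferon (0.66, 0.00264), HOX (0.40, 0.00414) and MHC class II genes (1.85, 0.0181) were higher. MYC and ribosome genes stood at -0.31 (adjusted p = 0.0157, adjusted p = 0.119 with an estimated correlation) although MYC itself rose. Calls also ended with an estimated correlation for receptors (0.15, adjusted p = 0.0186 to 0.146), lysosome genes (0.15, 0.0157 to 0.157) and the mitochondrial chain (-0.41, 2.16e-08 to 0.133).

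In the treated OCI-AML3 cells the ERK output list was not called between 2 and 24 h. DUSP6 (-0.26), SPRY2 (-0.23), MYC (-0.36) and EGR1 (-0.91) were not called, though EGR1 was without 24 h replicate 1 (-1.18), and ETV4 (-5.08), CCND1 (-2.11), BCL2 (-1.41) and ETV5 (-1.32) fell further. BMF rose (1.10). SPRY4 rose by 1.08, a call that ended with a pseudocount of 1 CPM (0.58) and without 2 h replicate 4 (0.96), and the call of ETV5 also ended with that pseudocount (-0.72). The ERK output list stood at -0.22 (adjusted p = 0.559).

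This comparison called 2939 genes, 1516 higher and 1423 lower (10117 by adjusted p alone), and library totals moved the median of all genes from 0.01 to 0.11. HLA-DRA (6.39), H2AC19 (5.96 ± 1.70), JPH2 (5.26), HLA-DRB1 (4.95) and MUC20 (4.82) rose most. SLCO4A1 fell 103-fold (34.8 to 499), and CTXN1 (-5.13), TERT (-4.61) and CDC45 (-4.52) fell with ETV4. S phase (median -2.71, adjusted p = 5.24e-21, 35 of 35 lower), G2 and M phase (-2.10, 6.25e-17, 28 of 28 lower), MYC and ribosome (-1.34, 2.87e-14), heat shock (-1.37, 2.43e-08) and cholesterol genes (-0.58, 0.000393) were lower. Lysosome (0.69, 6.73e-06), monocyte (1.33, 7.97e-05), interferon (0.61, 0.00183), MHC class II (2.09, 0.00188) and FOXO genes (0.66, 0.00308) were higher. With an estimated correlation the calls ended for p53 targets (0.28, adjusted p = 0.0382 to 0.0658), receptors (0.64, 0.00228 to 0.0626), glycolysis (-0.77, 0.00233 to 0.181), stress response (-0.42, 0.00773 to 0.112) and mitochondrial chain genes (-0.75, 2.19e-09 to 0.112).

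**Figure D3:**
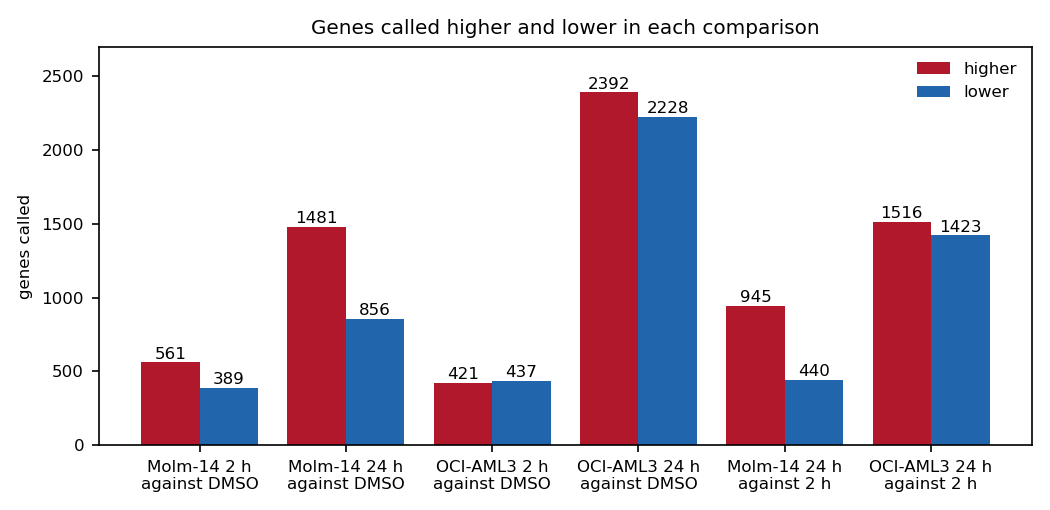
Number of genes (vertical axis) called higher (red) and lower (blue) in 6 comparisons, drug against DMSO and 24 h against 2 h in each line. OCI-AML3 at 24 h had 2392 higher and 2228 lower, and Molm-14 at 24 h had 1481 and 856.

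The lines differed before treatment. FLT3 was lower in OCI-AML3 (-2.45 ± 0.04), as were DUSP6 (-1.89), BMF (-1.45) and ETV5 (-1.42), and PHLDA1 (2.09), SPRY4 (1.97) and BCL2L11 (1.49) were higher. In DMSO 3932 genes differed, 2339 higher and 1593 lower in OCI-AML3 (10740 by adjusted p alone). BASP1, TIMP3, VCAN and MKX were at least 12800-fold, 10330-fold, 4352-fold and 3280-fold higher there and CYBB was higher by 10.44 ± 0.27. APP (-10.30 ± 0.27), SNRPN (at least 3336-fold) and DACH1 (at least 2805-fold) were lower. CCND1 (0.96), MYC (-0.68), BCL2 (0.56) and NRAS (-0.55) were not called.

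The drug responses of the lines overlapped at both times. Across 13033 genes, which are not independent replicates, the log2 fold changes had r = 0.579 at 2 h and 0.708 at 24 h, with separate DMSO controls. At 2 h 127 genes rose in both lines (18.1 expected), 207 fell in both (13.0 expected) and 7 went opposite ways. At 24 h the numbers were 1019 (272 expected), 731 (146 expected) and 40.

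**Figure D4:**
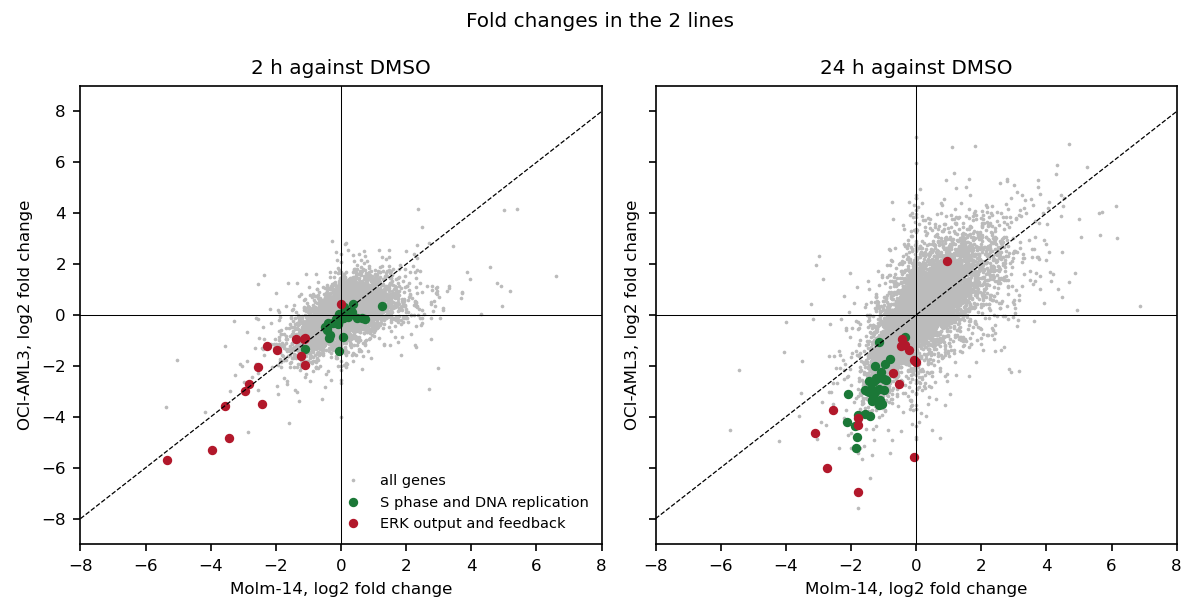
Log2 fold change of RMC-7977 against DMSO in Molm-14 (horizontal) and OCI-AML3 (vertical) at 2 h and 24 h; each point is 1 gene, with all genes in grey, S phase genes in green, ERK output genes in red, and a dashed line of equality. The correlation was r = 0.579 at 2 h and 0.708 at 24 h.

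At 2 h the responses differed in immediate early, S phase, FOXO target, HOX and RAS pathway genes. The difference passed for 735 genes, 276 with a higher and 459 with a lower change in OCI-AML3 (5039 by adjusted p alone). KLF2 (-5.06), CAMKK1 (-5.04), MAFA (-4.61), PTGDS (-4.27), RGS16 (3.28), FJX1 (3.02), EBF3 (2.69), IL12A (2.43) and OSR2 (2.39) differed most, with PSMC1P1 (-5.58 ± 2.12, adjusted p = 0.046), whose call ended with voom and without each of several libraries. EGR1 (1.75), CCND1 (-1.43) and DUSP6 (-1.35 ± 0.28) differed, and DUSP6 turned to 0.18 with a pseudocount of 1 CPM. With that pseudocount SPRY4, not called in the main fit (-0.36), was called (-1.35). Immediate early (median -0.45, adjusted p = 0.000416), S phase (-0.15, 0.000392), FOXO (0.48, 0.000406), HOX (0.27, 0.000649) and RAS pathway genes (-0.17, 0.00275) differed as lists, and ERK output was not called (0.07, 0.974). Calls that ended with an estimated correlation were G2 and M phase (0.15, adjusted p = 0.00455 to 0.157), interferon response (0.25, 0.0382 to 0.0549), cholesterol (-0.17, 0.0227 to 0.146) and heat shock (-0.20, 0.0023 to 0.0864).

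At 24 h the responses differed in ERK output, MYC, cell-cycle and metabolic genes. DUSP6 differed by -5.51 ± 0.29 (adjusted p = 5.0e-16), CCND1 by -5.17, ETV4 by -3.3, ETV5 by -2.25, MYC by -1.82, PHLDA1 by -1.69, SPRY2 by -1.58 and SPRY4 by -1.52. EGR1 (1.19) and BMF (1.02) differed in the other direction, and both calls ended with a pseudocount of 1 CPM (0.86 and 0.89). The call of EGR1 also ended without OCI-AML3 24 h replicate 1 (0.92). That of BMF ended without each of 3 DMSO libraries in turn (0.98 to 0.99) and with a replicate block (0.9997). The difference passed for 2325 genes, 1054 with a higher and 1271 with a lower change in OCI-AML3 (8527 by adjusted p alone), and with library totals the balance turned, to 1185 and 1130. LINC00939 (5.18), SLC7A11 (5.04), MAFA (-6.54), LGALS12 (-5.56) and NCF1C (-5.33) were among the largest beside DUSP6. S phase (median -1.63, adjusted p = 3.83e-20), MYC and ribosome (-1.25, 1.54e-15), G2 and M phase (-1.09, 2.41e-14), cholesterol (-1.52, 1.92e-13), glycolysis (-1.17, 1.48e-07), heat shock (-0.80, 9.24e-07) and ERK output genes (-1.63, 5.86e-05) had a lower change in OCI-AML3. In Molm-14 the cholesterol list stood above DMSO (median 0.50) and glycolysis near it (-0.13), while both stood below DMSO in OCI-AML3. MHC class II (1.26, 0.00179) and interferon response genes (0.43, 0.0186) changed further up, and monocyte genes were not called against other genes (-0.16, 0.973). An estimated correlation ended the calls of FOXO targets (0.33, adjusted p = 0.0154 to 0.0943), stress response (0.41, 0.00305 to 0.0805), lysosome (0.34, 0.000696 to 0.0565), receptor (0.37, 0.0211 to 0.15) and mitochondrial chain genes (-0.22, 0.032 to 0.593).

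Splits of the libraries tested how often mixed groups gave as many calls. In each of the 7 comparisons of a pair of groups the real split was the largest of 35, and the next had at most 1 call. Mixed groups carry a large difference into their own spread, so their few calls follow from the design and do not measure false calls. For the differences in response, exchange of treatment labels within lines gave as many calls in 2 of 100 splits at 2 h and 6 of 100 at 24 h, the latter above the share of 0.05 fixed for this test. Such an exchange can turn the drug effect of a line into a difference in response, so it cannot weigh chance there. With line means and the shared treatment effect removed, a test added after seeing the first, only the real split of 100 was that large at either time. What is left still holds the difference in response, which mixed draws carry into their own spread. Their few calls therefore follow from the design here too and do not measure false calls.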

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

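All tests of the 3 patterns weighed first were chosen only after the result was seen, and for the test of neighbouring genes alone the outcome each cause would give was written down before it was run. ERK output genes were low at 2 h in both lines, and at 24 h they had returned in part in Molm-14 (median -0.49) and stayed low in OCI-AML3 (-2.49). The median of the 24 h difference stayed at -1.56 with library totals and -1.62 with median-of-ratios scaling. The factors of these scalings were too small to move a median of this size. The choice among these scalings is thus not the cause, but the check cannot weigh a larger error of scaling. An exchange of the 2 h and 24 h libraries of Molm-14 is argued against by the S phase list, at -1.29 in the libraries named 24 h and -0.05 in those named 2 h. The DMSO group of a line cancels between 24 and 2 h, so its harvest time cannot make the return of 1.42 in Molm-14 (-0.22 in OCI-AML3). These values restate the pattern and do not test whether that harvest time shifts the levels against DMSO. A change with culture time remains open, since 0 untreated libraries have a time in the labels.

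HSPA6 and HSPA7 rose at 24 h in both lines. A heat shock response is argued against by the heat shock list, at -1.24 in Molm-14 and -2.04 in OCI-AML3. A constant share of reads from other HSP70 genes is argued against by the sum of HSPA1A, HSPA1B and HSPA8, at -1.76 and -3.07. In Molm-14 HSPA1A alone stood at 0.48 ± 0.59 and was not called. A growing share would itself lower that sum, so the sum cannot weigh it. Sharing between HSPA6 and HSPA7 was not tested. Each gene starts close downstream of an Fc gamma receptor gene, so transcription may run on into it. A rise upstream went with a rise downstream at an odds ratio of 1.6 in Molm-14 (Fisher exact p = 0.214) and 2.25 in OCI-AML3 (Fisher exact p = 0.0112), which leaves this open.

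Most replication-dependent histone genes rose at 24 h while S phase genes fell. Carry-over of RNA without a poly(A) tail is argued against in Molm-14 by the median of RN7SL1, RN7SL2 and RN7SK, at -1.97. In OCI-AML3 the median was -1.18, but none of these genes was called and RN7SK stood at 1.64 ± 1.78, so carry-over stays open there. A fixed pool of reads shared among the 17 measured histone copies is argued against by their summed CPM, up by 2.37 and 3.68. Histone copies that were not measured are outside that sum, so it cannot weigh reads shared with them. The scalings tried, with the small factors described above, were too small to be the cause and cannot weigh a larger error of scaling. They left medians between 2.08 and 3.71 over both lines and both scalings. A switch to polyadenylated histone transcripts in cells leaving the cycle could explain the rise but was not tested, because tails were not measured.

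Splits of the libraries gave as many calls as the real groups in 1 of 35 cases, the real split alone, for each of the 7 comparisons of a pair of groups. The few calls in mixed groups do not measure false calls, because a large difference enters their own spread. For the differences in response they did so in 2 of 100 cases at 2 h and 6 of 100 at 24 h, so by the limit of 0.05 fixed beforehand chance was not excluded at 24 h. These splits can turn the drug effect of a line into a difference in response, so they cannot weigh chance there. The highest other splits called 1740 and 5847 genes. The 1 and 5 other splits that reached the real count all kept or exchanged nearly all labels of a single line, a description made after they were seen. There were 7 and 16 other splits of that kind, so 6 and 11 of them did not reach the real count. A further test with the line means and the shared treatment effect removed, added after seeing the first, gave 1 of 100 at both times, with at most 316 and 0 calls in other draws. Those draws mix the groups and carry the difference in response into their own spread. Their few calls follow from the design and do not measure false calls.

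Among 230 groups of values, 10 values from 8 libraries stood apart from the others of their group, against 11.5 values expected by chance. OCI-AML3 at 24 h (n = 3) was not checked, because the check needed 4 libraries in a group. The share of the 10 highest genes was 8.94% in Molm-14 2 h replicate 4. ETV4 was at 1.74 log2 CPM in Molm-14 24 h replicate 1 and at 3.64 in OCI-AML3 2 h replicate 4. In OCI-AML3 DMSO, ETV5 (3.63) and CCND1 (6.04) stood apart in replicate 2, EGR1 (5.4) in replicate 1 and the G2 and M phase list (6.86) in replicate 4. MYC was at 6.32 in OCI-AML3 2 h replicate 4. The granulocyte maturation list was at 5.66 in Molm-14 DMSO replicate 2, and the MHC class II list at 3.07 in Molm-14 24 h replicate 4.

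Between times 1385 genes changed in Molm-14 and 2939 in OCI-AML3, and between lines the response of 735 genes differed at 2 h and that of 2325 at 24 h. At 2 h the lists that differed were immediate early (-0.45), RAS pathway (-0.17), S phase (-0.15), HOX and progenitor (0.27) and FOXO targets (0.48), and the genes were DUSP6 (-1.35), CCND1 (-1.43) and EGR1 (1.75). At 24 h they were S phase (-1.63), ERK output (-1.63), cholesterol (-1.52), MYC and ribosome biogenesis (-1.25), glycolysis (-1.17), G2 and M phase (-1.09), heat shock (-0.80), interferon response (0.43) and MHC class II (1.26). The genes at 24 h were DUSP6 (-5.51), CCND1 (-5.17), ETV4 (-3.3), ETV5 (-2.25), MYC (-1.82), PHLDA1 (-1.69), SPRY2 (-1.58), SPRY4 (-1.52), EGR1 (1.19) and BMF (1.02).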

How the results depend on the processing

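The tests with a pseudocount of 1 CPM, with median-of-ratios scaling, and with library totals for lists and correlations were chosen only after the results were seen. Without a bound on the fold change the counts were 7756, 9950, 8106 and 11002 for Molm-14 at 2 and 24 h and OCI-AML3 at 2 and 24 h against DMSO. They were 8901 and 10117 for 24 h against 2 h in the same order of lines, 5039 and 8527 for the differences in response at 2 and 24 h, and 10740 for the lines in DMSO. The threshold test against a fold of 1.5 called 3588 genes in Molm-14 at 24 h, and a pseudocount of 1 CPM called 562 in OCI-AML3 at 2 h and 470 in the 2 h difference in response, where DUSP6 turned to 0.18. Fry called 80 lists against DMSO and 82 in the family of times and lines, where an estimated correlation called 35. It placed 5 uncalled lists on the other side from camera, with medians of 0.0603 (BCL2 family, Molm-14 2 h), 0.0671 (granulocyte maturation, Molm-14 2 h), 0.0125 (p53 targets, OCI-AML3 2 h), -0.10 (NF-kB, OCI-AML3 24 h against 2 h) and -0.0385 (NF-kB, 24 h difference). The correlation between lines at 2 and 24 h was 0.594 and 0.751 by Spearman and 0.640 and 0.768 for genes of at least 10 CPM, and 0.706 at 24 h with library totals. Leaving out each library in turn gave 0.570 to 0.583 and 0.705 to 0.709. Replicate numbers did not pair libraries, with a median residual correlation of 0.0109. With the number as a block, the counts were 954, 2336, 857, 4620, 1383, 2937, 736, 2317 and 3959 in the order above, BMF lost its call in the 24 h difference, and 0 of 184 list tests changed. Of 636 named results, library totals ended 10 calls and added 11, median-of-ratios scaling ended 3 and added 4, voom ended 1 and added 2, and a pseudocount of 0.1 CPM changed 0. That pseudocount nearly equals the deposited lowest value of 0.105 CPM, so it could hardly differ from the main fit. Of 184 list tests, an estimated correlation ended 32, library totals ended 2 and added 5, and fry added 55. Leave-one-out fits ended 36 and added 11 of 5363 named results. The DESeq2 Wald test and its size factors, and a table with no filter on low counts, were not run. Genes with few reads limit the fold changes that depth can resolve, and a pseudocount of 1 CPM ended 16 of 636 named results and turned 1 more, DUSP6, which also lost its call. That pseudocount added 1 call, SPRY4 in the 2 h difference in response (-1.35, against -0.36 in the main fit). The cause was not tested.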

Other observations

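All genes here were chosen only after their values were seen, and the tests are those of the fit over all genes, fixed earlier. FCGR2A, FCGR2B and FCGR2C, neighbours on chromosome 1, rose at 24 h in both lines. FCGR2A went from 29.7 to 222 CPM in Molm-14 and from 62.2 to 190 CPM in OCI-AML3, and FCGR2C (chr1:161581339-161605662, plus strand) from 3.97 to 198 and from 10.5 to 170 CPM. HSPA6 (chr1:161524540-161526910, plus strand), which starts 526 bp after FCGR2A, went from 1.74 ± 0.25 (SD) to 61.7 ± 6.6 CPM in Molm-14 and from 10.6 to 90.2 CPM in OCI-AML3. HSPA7 (chr1:161606291-161608217, plus strand), 628 bp after FCGR2C, went from 3.34 to 243 and from 16.9 to 334 CPM. FCGR2B (chr1:161663147-161678654, plus strand) rose by 5.65 in Molm-14 and 3.15 in OCI-AML3, and FCRLA by 2.83 and 2.31. FCRLB rose by 1.36 in Molm-14 and was not called in OCI-AML3 (0.24). At 2 h none of these genes was called, while HSPA1B and HSPA8 fell at 24 h in both lines.

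Most histone genes of the replication-dependent clusters rose at 24 h as DNA replication genes fell. Of 17 measured, 12 rose and 1 fell in Molm-14 (median 2.02), and 15 rose and 1 fell in OCI-AML3 (median 3.55). H2AC6 rose by 4.3 and 5.53, H2BC5 by 3.74 and 5.05 and H2BC12 by 2.2 and 3.49, whereas H2AC20 fell (-1.45 and -1.94). Their summed level went from 14.6 to 75.5 CPM in Molm-14 and from 33.9 to 435 CPM in OCI-AML3.

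Of 13 measured Krüppel-like factor genes, which were not a fixed list and were not tested as a group, 7 rose at 2 h in Molm-14 and 1 in OCI-AML3, and the response of 5 differed. At 24 h 5 rose in Molm-14 and 7 in OCI-AML3. In Molm-14 at 2 h KLF2 (6.61), KLF3 (2.56), KLF6 (2.33), KLF13 (1.91), KLF7 (1.77) and KLF11 (1.17) rose. In OCI-AML3 at 2 h KLF2 rose by 1.54, and KLF7 (0.94), KLF13 (0.49), KLF6 (0.36), KLF11 (0.12) and KLF3 (0.05) were not called. The difference in response passed for KLF2 (-5.06), KLF3 (-2.51), KLF6 (-1.97), KLF13 (-1.43) and KLF11 (-1.06). The lines already differed in DMSO, where 4 of the 13 genes were called higher in OCI-AML3 and 2 lower. KLF2 was among the higher ones, with a mean of 58.3 CPM in OCI-AML3. At 24 h KLF2 (4.69), KLF13 (1.65), KLF6 (1.63) and KLF7 (1.5) were still higher in Molm-14. In OCI-AML3 at 24 h KLF2 (1.31) was still higher, and KLF13 (1.32), KLF7 (1.22) and KLF11 (1.13) were called there as well. KLF4, KLF5 and KLF9 also rose there. The 24 h change was higher in OCI-AML3 for KLF4 and KLF5 and lower for KLF2, KLF6 and KLF12.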
